A study of Mus musculus with 12 samples.

How the data were processed

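RNA was measured in whole-RNA extracts of mouse brain from 12 samples, 6 after intracerebral hemorrhage (ICH, bleeding into the brain) and 6 after a sham operation, all from female wild-type mice aged 12 weeks. Per the labels, RNA was extracted with Trizol and sequenced from libraries of a stranded total RNA kit primed with random hexamers, and the series' design text gives day 3. The brain region, the way the bleeding was induced and the strand setting of the read counting are not given in the sources used here. The labels number the samples of each group but do not say that each came from a separate mouse, so p-values measure the spread between these samples.

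Per the submitters' processing notes, which give no roles or order, the authors used CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and edgeR with build mm10. The single table used here holds 2031 genes, one column per sample and columns of the authors' own comparison. The sample columns hold a signal that the values and the deposited tool names point to as gene read counts adjusted by the authors to a common library size; this was inferred, since no header states it. The authors' deposited table also gives log2 fold changes, p-values with adjusted p-values, coordinates and biotypes. Every listed gene has an adjusted p-value under 0.05 and an absolute log2 fold change above 1 in the authors' deposited table. The adjusted p-values there correspond to 30120 tested genes. A gene outside the table therefore missed a threshold or was not tested, and every test described here was run on genes already chosen from these same samples. Coordinates were equal to those of GENCODE M21 for 1960 of the 2030 gene identifiers found in it.

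Library totals are unknown because only listed genes have values, so no depth, counting interval or detection limit is given. Sums of the listed genes are not depths. With a tolerance of 0.02 on values under 20, a single step per library gave whole numbers for over 99% of low values in 2 libraries (the second of them 99.5%) and for 8.60% to 53.2% in the other 10, so whole reads were not recovered and no count test was run. The fixed design foresaw this case and named limma.

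Values were analysed as log2(value + 1) in limma 3.58.1 (R 4.3.3) with an intensity trend in the variance prior, ICH against sham, without covariates, two-sided. Benjamini-Hochberg adjustment ran over the 2031 listed genes and genes were called at adjusted p under 0.05. The variance prior was estimated from the same chosen genes. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. No pairs of samples held identical values, and the highest correlation between 2 samples was 0.965.

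The 24 gene lists with 360 genes, the tests, the naming rule and the main alternatives were fixed before the data were examined. Each list was counted over all listed genes and over the list alone. A Fisher exact test compared higher against lower members of a list with the other listed genes, for lists with at least 5 listed members. A list score, the mean of log2(value + 1) over listed members, was compared between groups with a two-sided exact permutation test over all 924 assignments, for lists with at least 3 listed members. A comparison of a list with unlisted genes was not possible. The lists served as marker lists in whole-tissue RNA and no cell type share was estimated. List names therefore do not say which cells gave the RNA, or whether cell number or expression per cell changed. Named genes were the 5 largest rises and 5 largest falls by limma log2 change among called protein-coding genes whose groups did not overlap and whose higher group mean was at least 50, and for each list the 2 members with the smallest p, or 3 where at least 8 were called. The rule gave a minimum of 50 for counts and 1 for normalized units. The value of 50 was applied because these signals are on a count scale, a choice made after the unit was seen. Symbols of predicted genes were not treated as names. The rule gave 53 genes, of which 1 is not reported here.

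Correlations of other list scores with the macrophage score within the ICH samples had also been planned. They were computed and then withheld, because 2 of the 6 ICH samples stood apart from the other 4 on the macrophage score. A correlation of that score with thalamic marker genes was withheld for the same reason.

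The limma step was tested on simulated data for ICH against sham with the 2031 listed genes and 50 changed genes per fold size. It recovered 11 genes at 1.5-fold, 33 at 2-fold, 43 at 4-fold and 45 at 8-fold, and called 2 of 1831 unchanged genes. Both groups were simulated from the means and spread of the sham samples, with most genes unchanged. The real genes had been chosen by this contrast, so these rates do not carry over to them. Alternatives were quantile normalization, a minimum mean of 10, pseudocounts of 0.5 and 5, an adjusted p under 0.01, a fold change of at least 2, the replicate number as a block, and each sample left out in turn. Adjustment over all 30120 genes, with unlisted genes counted as not significant, and a fit without sham replicates 2 and 6 were added after the data were seen. Marker genes of brain regions and gene families in the closing observations were also chosen after the data were seen. Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9 was used for the other steps.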

Results

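Gene expression was compared in brain RNA of female mice at day 3, in 6 samples after ICH and 6 after a sham operation, to ask which transcripts differ in the acute stage after bleeding. The values are library-size-adjusted read counts for the 2031 genes that the authors had called, so the account describes the authors' chosen genes and does not test them independently. Summed over these genes, the ICH samples held 596483 to 1338830 adjusted counts and the sham samples 334144 to 409288. Library depth is unknown.

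The rising genes included genes of macrophages, neutrophils, reactive astrocytes, extracellular matrix and the cell cycle, and the falling genes included Wnt9b, Tnnt1 and Rgs9. In limma, 1729 genes were higher and 293 lower in ICH at adjusted p under 0.05. The authors' deposited table lists 1734 genes with a positive and 297 with a negative log2 fold change, from -5.39 to 8.16, with medians of 1.93 for rising and -1.42 for falling genes. Of the listed genes 1699 were protein-coding, 1536 of them higher and 163 lower, while the 101 lincRNA genes were divided into 55 higher and 46 lower. In 1231 genes all ICH samples lay above all sham samples, and in 132 all lay below, together 67.1% of the genes against 0.216% by chance for genes not chosen by this contrast. Quantile normalization shifted the median log2 difference of the listed genes from 1.58 to 0.13 and gave 495 higher and 365 lower genes, because it forces equal distributions on a list in which 85.4% of the genes rise. The directions below hold for the values as deposited, and members whose sign turned under quantile normalization are named.

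Under the naming rule and on the log2(value + 1) scale, the largest rise was in Arg1 (arginase 1, an enzyme of alternatively activated macrophages; chromosome 10, 24915221 to 24927484, mm10), from 22.8 ± 18.0 adjusted counts in sham to 2386 ± 1974 in ICH (SD, n = 6 each; log2 difference 6.45, SE 0.49; limma adjusted p = 4.55e-09). Chil3, a chitinase-like protein of myeloid cells, rose by 5.66 on the log2 scale from 4.66 ± 5.73 to 235 ± 159. Cxcl2, a neutrophil-attracting chemokine, rose from 0.492 ± 0.804 to 120.0 ± 123 (log2 5.46, with a ratio of group means of 244 against 104 for Arg1), Selp, the adhesion molecule P-selectin, from 3.61 ± 3.07 to 343 ± 447 (log2 5.40), and Clec4d, a C-type lectin receptor, from 5.59 ± 2.59 to 326 ± 234 (log2 5.38). The ICH samples were far apart in these genes, with SDs near or above the mean for Cxcl2 and Selp. Single samples carried part of some means, as the ICH mean of Selp was 184 without ICH replicate 3, and the sham means of Chil3 and Cxcl2 were 2.55 without sham replicate 6 and 0.206 without sham replicate 3.

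Falling genes changed less. Wnt9b, a Wnt ligand (chromosome 11, 103727364 to 103749821), had the largest fall under the naming rule, from 96.9 ± 31.8 in sham to 11.6 ± 6.95 in ICH (n = 6 each; log2 -3.06, SE 0.35; limma adjusted p = 3.17e-07). Atp2a1, a calcium pump of the sarcoplasmic reticulum, changed by -2.36, Fam19a4 by -2.14, Tnnt1, a troponin T gene (chromosome 7, 4504570 to 4516382), by -2.08 and Vipr2, a receptor for vasoactive intestinal peptide, by -2.02 on the log2 scale. Among the falling genes were also the pituitary hormone genes Gh and Prl, named here after their values were seen, for which 90.8% and 83.7% of the sham total came from sham replicates 4 and 6.

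**Figure D1:**
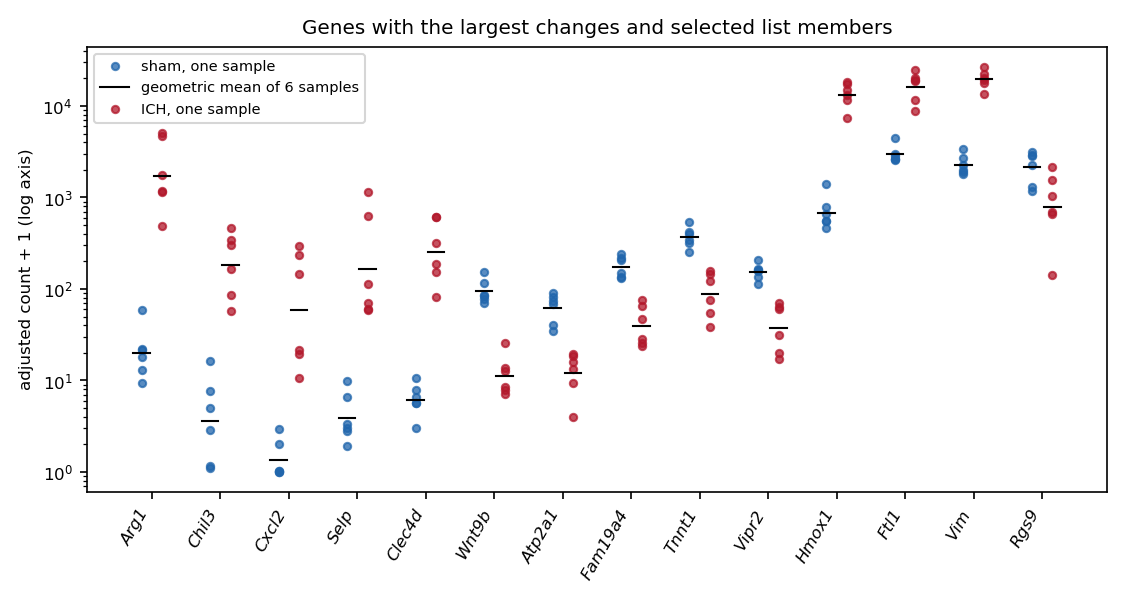
Adjusted counts plus 1 (log axis) of the 10 genes with the largest changes under the naming rule and of 4 further list members picked for display, one point per sample and a bar at the geometric mean of each group. Arg1 averaged 2386 in ICH against 22.8 in sham, and Hmox1 13803 against 732.

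Genes of macrophages and phagocytes were among those called higher. Of 13 genes of infiltrating monocytes and macrophages, 10 were listed and 9 were called higher, with F13a1, a coagulation factor subunit made by monocytes, at 601 ± 478 against 23.6 ± 7.20 (log2 4.24, SE 0.44). Ly6c2 was listed but not called (limma adjusted p = 0.144) and turned negative under quantile normalization. All 15 listed of 18 phagocytic and lipid-handling genes were called higher, among them the scavenger receptor Msr1 (log2 4.58, SE 0.28), Lgals3 (log2 3.41) and Cd68 (log2 2.32), with Ctsb turning negative under quantile normalization. Of 12 homeostatic microglia genes, 6 were listed and all 6 were called higher, with Fcrls at log2 2.19 and Olfml3 at log2 1.80, and Tmem119 turning negative under quantile normalization. P2ry12, Sall1, Siglech, P2ry13, Gpr34 and Selplg were not listed, so the list as a whole cannot be said to have risen.

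Neutrophil and chemokine genes were also higher. Of 13 neutrophil genes 7 were listed and 7 called higher, including the collagenase Mmp8 (88.7 ± 54.0 against 4.17 ± 3.27, log2 4.07) and S100a8, a calcium-binding protein of granulocytes (158 ± 148 against 7.54 ± 5.01, log2 3.90). Ly6g, Mpo, Elane, Ngp, Camp and Ltf were not listed. Of 20 cytokine and chemokine genes 19 were listed and called higher, with Ccl2 at log2 4.59 (SE 0.39), Ccl7 at 3.97 and Ccl12 at 3.46, while Lif and Csf1 turned negative under quantile normalization. Of 14 lymphocyte genes 5 were listed and called higher, all at low levels. Ms4a4b reached 20.9 ± 23.1 against 1.06 ± 1.35 and Cd3g, a subunit of the T cell receptor complex, 6.77 ± 7.74 against 0.185 ± 0.451, and Cd3g was no longer called under quantile normalization. ICH replicates 1 and 3 had the highest values, 61.1 and 36.1 for Ms4a4b against 3.68 to 12.7 in the other 4, and 12.4 and 20.1 for Cd3g against 0.941 to 2.90. The ICH mean was 12.8 for Ms4a4b without replicate 1 and 4.11 for Cd3g without replicate 3, and without sham replicate 5 the sham means were 0.603 and 0.00099. Adjusted over all 30120 genes the authors tested, with unlisted genes counted as not significant, 3 of these 5 passed.

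Complement, interferon and antigen presentation genes followed the same direction. All 14 listed of 16 complement genes were called higher, with the receptors C5ar1 (log2 3.81), C3ar1 (log2 2.98) and Itgb2 (log2 2.64). All 16 listed of 18 interferon response genes were called higher, with Bst2 and Ifitm3 each at log2 2.32 and Gbp2 at 1.83, while Rsad2 and Usp18 turned negative under quantile normalization and Gbp2 was no longer called. Of 13 antigen presentation genes 12 were listed and 11 called higher, with the immunoproteasome subunit Psmb8 at log2 2.23, the class I heavy chain H2-K1 at 1.65 and its partner B2m at 1.42 (6639 ± 1595 against 2437 ± 364). Ciita was not called (limma adjusted p = 0.0623) and turned negative with Tap2 under quantile normalization.

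Genes of heme breakdown and iron storage reached some of the highest levels. Hmox1, heme oxygenase 1 (chromosome 8, 75093621 to 75100589), rose from 732 ± 340 to 13803 ± 3936 (n = 6 each; log2 4.28, SE 0.25; limma adjusted p = 4.84e-10), the smallest p of the limma fit. Ftl1, the ferritin light chain, rose from 3021 ± 729 to 17241 ± 5964 (log2 2.46), and Slc11a1, a metal transporter of phagosomes, by 2.82 on the log2 scale. In all, 11 of 23 heme, iron and antioxidant genes were listed and called higher, of which Slc40a1, Blvrb, Steap3 and Mt1 turned negative under quantile normalization. The other 12 were not listed, among them Fth1, Nqo1, Gclm, Gclc, Srxn1, Txnrd1, Slc7a11 and Gpx4. The list as a whole therefore cannot be said to have risen. None of 10 erythroid and blood RNA genes was listed, 1 of which, Ahsp, is not in the annotation under that symbol. Reads of Ftl1, H2-K1 and Hspa1a can be shared with near-identical copies, so their values are uncertain.

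Reactive astrocyte and matrix genes rose, while baseline astrocyte genes were not listed. Of 20 reactive astrocyte genes 19 were listed and called higher, with the intermediate filament Vim at 19974 ± 4322 against 2351 ± 620 (log2 3.09, SE 0.20), Tgm1 at log2 4.77 and the protease inhibitor Timp1 at log2 4.47. None of 10 baseline astrocyte genes was listed. Which cells gave the RNA of the reactive astrocyte genes was not determined. Of 22 extracellular matrix genes 20 were listed and called higher, including Thbs1 (log2 4.38) and Tnc (log2 1.97), with Col4a2, Col5a1 and Bgn turning negative under quantile normalization. Of 17 endothelial genes 9 were listed and called higher, among them Icam1 (log2 2.48) and Vwf, von Willebrand factor (log2 2.43), with Pecam1, Cdh5, Vcam1 and Angpt2 turning negative under quantile normalization.

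All 17 cell cycle genes were listed and called higher. Cdk1, the mitotic kinase, rose from 37.5 ± 14.8 to 371 ± 120 (log2 3.27), Rrm2, a subunit of ribonucleotide reductase, by 3.18 and Ccnb1, cyclin B1, by 3.14 on the log2 scale. Of 17 inflammasome and cell death genes 11 were listed and called higher, with the necroptosis kinase Ripk3 at log2 4.29, Pycard at 2.10 and Casp8 at 1.95, while Tnfrsf10b and Cdkn1a turned negative under quantile normalization. Of 8 heat shock genes Hspa1a alone was listed and called higher (log2 1.10), and it changed by -0.43 under quantile normalization.

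Neuronal and oligodendrocyte lists were nearly absent from the table. None of 17 general neuron genes, 12 myelin genes, 8 oligodendrocyte precursor genes or 12 choroid plexus and ependyma genes was listed, which says only that each missed a threshold or was not tested. Of 15 striatal projection neuron genes Rgs9 was listed and called lower (1034 ± 709 against 2288 ± 853, log2 -1.45, SE 0.45). Its groups overlapped, and without ICH replicate 1, which was at 141 while the other ICH samples were at 654 to 2127, the log2 difference was -0.96. Of 15 immediate-early genes the transcription factor Atf3 was called higher (log2 2.35) and Npas4 lower (log2 -1.23). Neither Rgs9 (adjusted p = 0.0776) nor Npas4 (adjusted p = 0.0546) passed in limma when adjusted over all 30120 genes, with unlisted genes counted as not significant. In the authors' deposited table their adjusted p-values were 0.0256 and 0.00656.

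**Figure D2:**
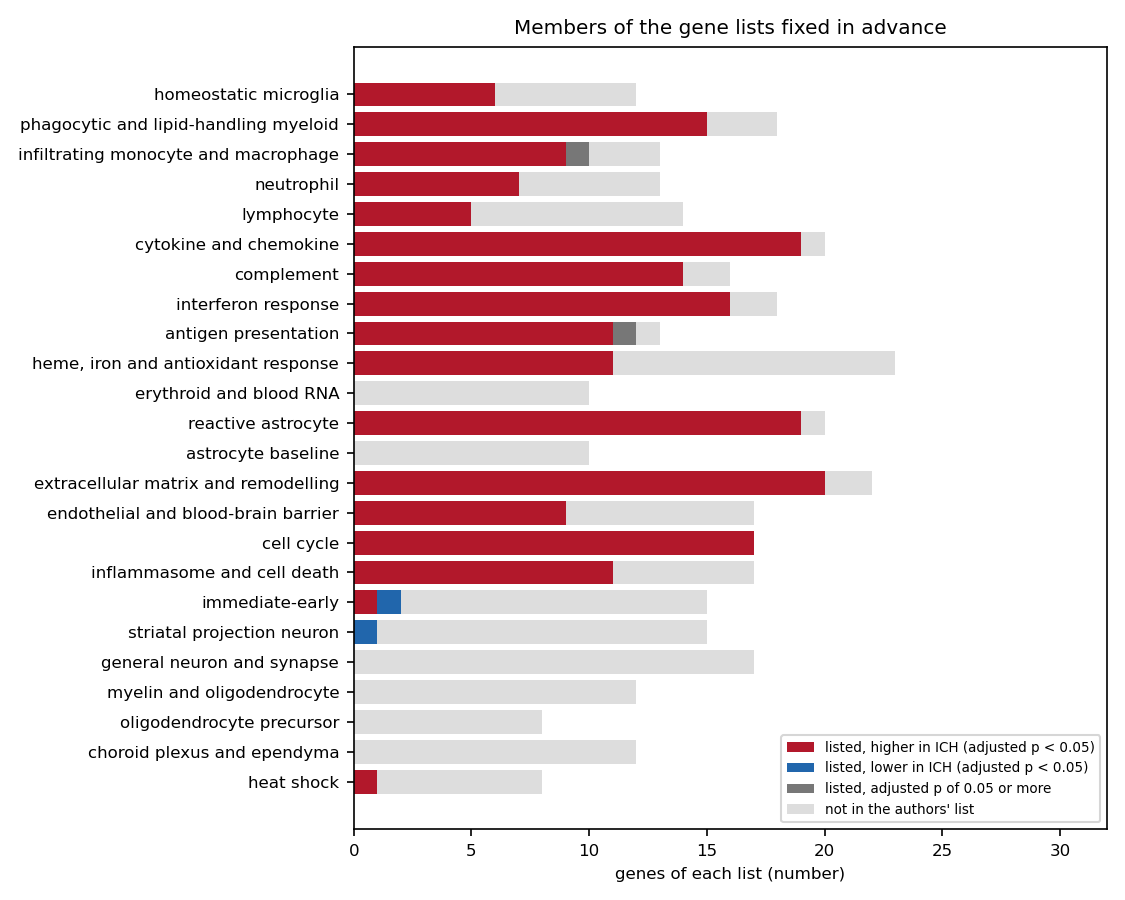
Number of genes in each of the 24 lists (horizontal axis) that were listed by the authors and called higher or lower in ICH, listed but not called, or not listed. All 17 cell cycle genes were higher and none of the 17 general neuron genes was listed, and some members of 11 lists turned negative under quantile normalization.

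Counts adjusted over the list alone were the same as those over all listed genes in all 24 lists, but are not independent evidence because the authors' selection used the same samples. Of the 195 list members in the table, 193 had a positive and 2 a negative difference. As 85.4% of the table rose, none of the 15 lists tested differed from the other genes in its split of higher and lower genes (Fisher's exact test, adjusted p = 0.392 to 1). All listed members of these lists were already higher, and the smallest unadjusted Fisher p was still 0.0963. The test could therefore not have found a list richer in rising genes than the rest, and no conclusion is drawn from it.

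List scores separated the groups in each of 15 lists, with all 6 ICH samples above all 6 sham samples. Differences ranged from 1.45 for homeostatic microglia (11.42 ± 0.32 against 9.97 ± 0.19) to 3.61 for monocytes and macrophages (7.57 ± 1.23 against 3.96 ± 0.41). The exact permutation p was 0.00216 for each list, also after adjustment over 15 lists, which is the smallest the design can give. Only listed members enter a score, and the authors had chosen them by this same contrast. The separation and its p are therefore not independent evidence, and the differences leave out all unlisted members. ICH replicate 3 had the highest score in 14 lists and ICH replicate 1 in the remaining list, while ICH replicate 6 had the lowest ICH score in 14. On the macrophage score, ICH replicates 1 and 3 lay 5.16 and 5.18 above the sham mean and the other 4 between 2.37 and 3.20, and on the lymphocyte score 3.84 and 3.48 above it and the other 4 between 1.06 and 1.45. The gap of 1.96 on the macrophage score took 69.9% of the range, so the planned correlations of other list scores with the macrophage score across the 6 ICH samples are not given.

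**Figure D3:**
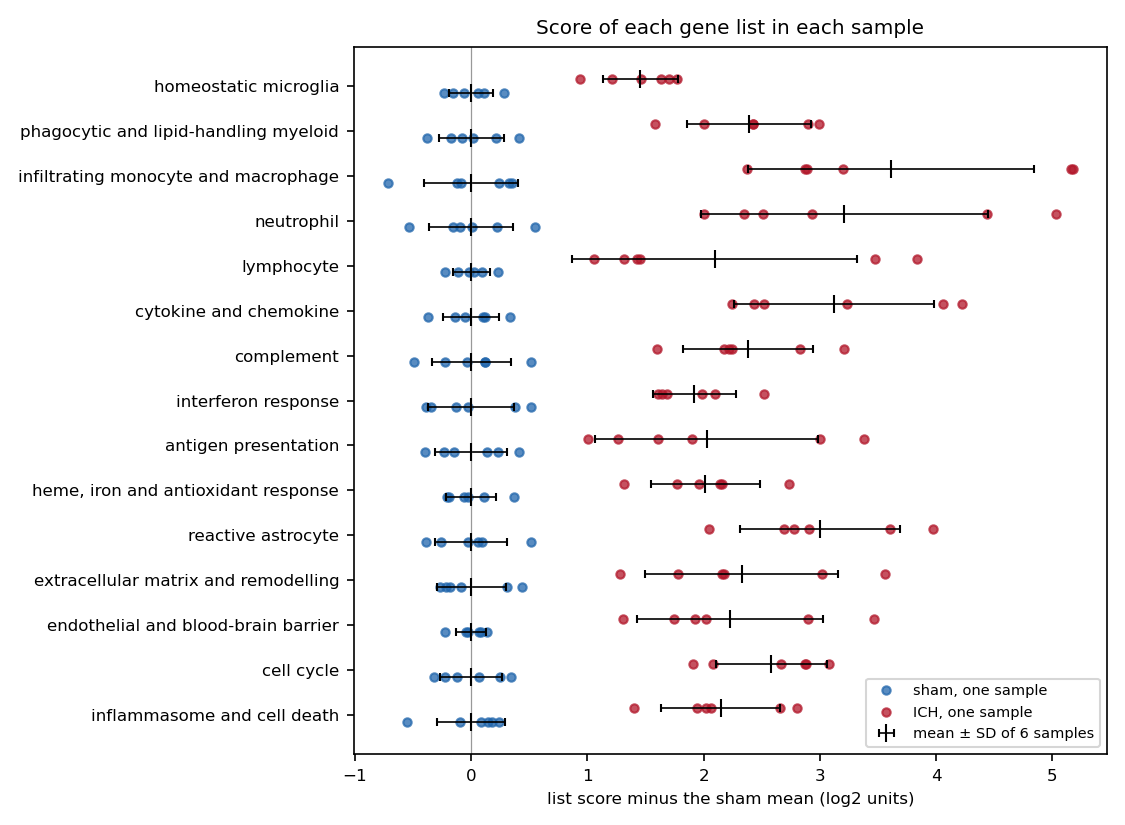
Score of each gene list in each sample, as the difference from the sham mean in log2 units, with the mean and SD of the 6 samples of each group. The 6 ICH samples lie above the 6 sham samples in all 15 lists, with differences of means from 1.45 to 3.61. Only listed members, which the authors had chosen by this contrast, enter a score.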

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

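The tests on ICH replicate 6 and the repeated grouping of samples were chosen after the results they concern had been seen. Dixon's test at the 95% level was applied to 136 groups of 6 values, 15 list scores and 53 named genes in each group of samples. It marked 12 values where about 6.8 are expected by chance, 1 in 20, if values are normally distributed. Named genes were tested as adjusted counts and not on the log2 scale, and skewed counts can raise the number of marks. The marked genes below may therefore not stand apart on the log2 scale.

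Among sham samples, replicate 5 stood above the others in Arg1 (58.1 against at most 21.2), Cd3g (1.11 against at most 0.00496) and Cdk1 (67.0 against at most 35.1). Sham replicate 2 was high in the heme and iron genes Hmox1 (1390 against at most 782) and Ftl1 (4469 against at most 3022). Sham replicate 6 was high in Mmp8 (10.4 against at most 3.99) and low in Pycard (38.8 against at least 72.6). Sham replicate 4 was high in Icam1 (83.9 against at most 56.2) and sham replicate 1 in Ripk3 (9.98 against at most 3.36).

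Among ICH samples, replicate 3 was high in the interferon-inducible genes Ifitm3 (2510 against at most 1452) and Gbp2 (549 against at most 377). ICH replicate 6 kept the most Wnt9b (24.7 against at most 12.7).

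ICH replicate 6 also had the lowest ICH score in 14 of 15 lists. Its rising genes lay a median of -0.77 on the log2 scale from the mean of the other ICH samples. Its falling genes lay 0.25 above them (95% bootstrap interval over genes 0.18 to 0.31, and genes are not independent replicates). The same median ran from -0.40 in ICH replicate 1 to 0.26 in ICH replicate 4, so 0.25 is within the spread of the other ICH samples. It still argues against library scaling in ICH replicate 6, as scaling moves rising and falling genes in one direction. Of its rising genes 83.3% exceeded every sham sample, against 91.0% to 98.0% in the other ICH samples, which argues against a sham library under an ICH label. The rising genes had been chosen with this sample counted as ICH, which can raise that share, so it is not independent evidence. A smaller response in this sample may remain as a hypothesis; lesion size was not analysed here.

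Across 100 of the 462 splits of the 12 samples, 1 split, the real one, called as many genes as the real 2022, and the highest other split called 1507. As the genes had been chosen by the real split, this comparison cannot say whether chance is excluded.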

How the results depend on the processing

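The adjustment over all 30120 genes the authors tested and the fit without sham replicates 2 and 6 were added after the data were seen. Of 42 alternative counts of higher and lower genes, 40 stayed within 1.5 times the main counts. Quantile normalization gave 495 higher genes in place of 1729, by its construction on a list of mostly rising genes. Adjustment over all 30120 genes gave 173 lower genes in place of 293. Unlisted genes were counted as not significant there. The authors' p-values and adjusted p-values place 4958 tested genes at or below the largest listed p, and 2927 of these are not listed. The adjustment may therefore be too strict, and calls lost under it are not shown to be false. It left 3 lymphocyte genes higher, 0 immediate-early genes lower and 0 striatal genes lower. The other 301 of 304 list counts stayed within that bound. These list counts were not repeated under quantile normalization, the other pseudocounts, the minimum mean or the fold minimum, so they say nothing about those settings. Each of the 255 alternative list scores kept its direction and its side of the threshold, which says little since the members were chosen by this contrast and the main p is the smallest possible. Apart from standardised genes, which are on another scale, the size moved by over 1.5 times for the lymphocyte score (2.09 to 0.995 with a pseudocount of 5) and the endothelial score (2.23 to 1.41 with the median over members). Quantile normalization lowered the median log2 change of listed members further. It fell from 1.70 to 0.21 for heme and iron genes, from 1.26 to 0.25 for homeostatic microglia and from 3.49 to 2.12 for monocytes and macrophages. The median stayed above 0 in all 15 scored lists. Of 1006 alternative values of named genes, 1001 kept their direction and their side of the threshold. Hspa1a reversed to -0.43 under quantile normalization, where Cd3g and Gbp2 also lost their calls, and Npas4 and Rgs9 lost theirs under adjustment over all tested genes. Leaving out each sample in turn gave 1712 to 1726 higher and 284 to 295 lower genes. Without sham replicates 2 and 6 the counts were 1685 and 277.

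The values gave no sign that the replicate numbers pair the samples, though a small shared effect cannot be excluded. Deviations of samples with the same number correlated from -0.22 to 0.23, and 1 of 6 ICH samples correlated best with its own number. With the replicate block, 1728 genes were higher and 294 lower. Standardised scores for the correlations with the macrophage score are not given, since those correlations were withheld after they had been computed. Alternatives meant for raw counts were not run because the values are adjusted. No setting here removes the selection of genes by the authors, and the unknown depth leaves the counting error of low genes open.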

Other observations

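The families, regional markers, hormone genes and all tests in this part were chosen after the data were seen, so none is independent evidence. Of all listed genes 85.4% rose, so a family with few listed members is likely to be all higher, and the counts below are descriptive. Of 27 gene families counted, 20 had all their listed members higher and 6 had a lower member, and those named here are a selection. Among the former were receptor families of myeloid cells. Listed and called higher were 9 of 19 Ms4a genes, 9 of 12 Toll-like receptors, 8 of 9 leukocyte immunoglobulin-like and paired receptors, and 4 of 5 Fc gamma receptors. The same held for 10 of 18 cathepsins, 8 of 14 S100 genes and 6 of 9 Schlafen genes. Of genes of chromosome segregation, 9 of 21 centromere proteins and 11 of 39 kinesins were listed and higher. Under quantile normalization Tlr9, Ctsb, Slfn5, Cenpl, Cenpn, Kif15 and Kif20a turned negative. By contrast only 2 of 76 cytosolic ribosomal protein genes and 0 of 46 genes of respiratory complex I were listed. The ribosomal genes, Rpl7a and Rps27l, were called higher but turned negative under that normalization. Tlr2 rose by 3.31 on the log2 scale (697 ± 334 against 66.0 ± 18.6, n = 6 each). The authors' deposited table marks 87 listed genes as transcription factors, 70 higher and 17 lower. The myeloid factors Spi1 (log2 2.27), Runx1 (2.15) and Irf8 (1.73) were among the higher ones. Of 15 GABA-A receptor subunits 3 were listed, Gabra4 (log2 -1.24), Gabrd (-1.17) and Gabrq (-0.93), all lower.

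A set of the falling genes are markers of the thalamus. Of 19 thalamic markers 13 were listed, all lower, against 8 of 87 markers of other regions, all lower (Fisher's exact test p = 2.08e-07, on a list written after the falling genes had been seen). They included Tnnt1 (log2 -2.08), Ramp3 (-1.96), Synpo2 (-1.69), Ntng1 (-1.67), Prkcd (-1.59) and Tcf7l2 (-1.10). Their mean score was 8.89 ± 0.37 in ICH and 10.36 ± 0.29 in sham (n = 6 each), a difference of -1.47 with an exact permutation p of 0.00216, the smallest possible.

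Dilution of brain RNA by RNA of incoming cells predicts one common fold if those cells carry none of these transcripts. The spread of the 13 log2 changes over their standard errors gave Q over its degrees of freedom of 1.78 (chi-square approximation over 13 genes, p = 0.0449), a narrow result that ignores error shared by genes of a sample. A second test was therefore added after that value was seen, and gave an exact permutation p of 0.00433 for unequal falls. Both argue against dilution alone by cells without these transcripts, though the authors' fold minimum also shapes which genes could be compared. Whether incoming cells carry some of them was not tested, and dilution by such cells could give unequal falls. Dilution would also lower other brain transcripts that incoming cells lack. The common log2 change of the 13 genes was -1.44. None of 17 general neuron, 12 myelin or 10 baseline astrocyte genes was listed. These counts argue against dilution alone for falls of that size. Each of these unlisted genes missed a threshold or was not tested, so the size of its change is unknown. Tissue from the base of the brain in sham replicates 2 and 6 does not account for the difference, which was -1.39 without them (exact permutation p = 0.00476 with n = 6 and 4, the smallest possible). Those 2 were picked by Oxt, and sham replicate 4, which was high in Gh and Prl, was kept. Such tissue in sham replicate 4 was therefore not tested. The lowest sham score was 9.99, in sham replicate 1, against at most 9.25 in ICH. A different piece of brain taken in the 2 groups cannot be told apart from loss or silencing of thalamic neurons, since both lower all these markers. The SD of sham scores was 0.198 of the group difference, and a lesion reaching the thalamus may be one explanation that no value here decides.

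Hormone genes of the pituitary and hypothalamus varied between sham libraries. The 2 highest sham libraries held 90.8% of the sham total of Gh, 83.7% of that of Prl and 97.1% of that of Oxt, a median of 90.8%. Gh reached 187 and 80.1 in sham replicates 6 and 4 and at most 16.4 in ICH, while Oxt reached 852 and 518 in sham replicates 6 and 2 and at most 29.7 in ICH. In limma Gh (adjusted p = 0.0166) and Prl (0.0290) were called lower and Oxt (0.476) was not. Gh and Prl have adjusted p-values under 0.05 in the authors' deposited table, as every listed gene has. Their limma calls are lost when adjusted over all genes the authors tested, with unlisted genes counted as not significant. Npas4, with a smaller limma adjusted p (0.00368), already missed the threshold there (0.0546). Trh, the other listed hypothalamic hormone gene, was called lower (log2 -1.17, adjusted p = 0.0178), a call lost under that adjustment for the same reason. Trh was also highest in sham replicates 6 and 2 (514 and 228, against at most 138 in ICH), and had 69.0% of its sham total there. It was not part of the median, and its share is under the bound given next. Small amounts of neighbouring tissue in a few sham libraries may explain the values of Gh, Prl and Oxt, but the bound of 80% behind this reading was set after the values were known, and a hormonal difference between the sampled mice was not tested.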
